A study of Homo sapiens with 30 samples.

How the data were processed

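RNA was measured in 30 libraries, which were 10 T cell populations sorted by flow cytometry from the peripheral blood of 3 healthy donors. The protocol selected mRNA by its poly(A) tail, barcoded it at reverse transcription, amplified it with T7 polymerase, fragmented the RNA and ligated an adaptor to its 3' end. The replicate number in the labels is the donor, so that each population had 3 libraries. The populations are named here as CCR6, CM (central memory), CXCR3_CCR4, naive, Th1, Th1_17, Th17, Th2, TSCM_CCR4 and TSCM_CXCR3, where TSCM stands for transitional stem cell memory. The labels give the chemokine receptors of the CCR6, CXCR3_CCR4 and TSCM gates only, and the receptors commonly used to sort Th1, Th2, Th17 and Th1_17 cells are a convention of the field. The column headings of the deposited counts name the CM libraries CM_NEG, and which markers were negative is not stated. No sequencing or library batch is given in the labels.

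The authors deposited raw read counts per gene symbol in 1 table, with 1 column per library. Their notes name STAR 2.7.3a and GRCh38, whereas the column headings name hg19, and no position of a gene is therefore given. The read counter, the annotation and any use of molecular identifiers are not stated. The table held 55765 genes and 5 summary counts of reads assigned to no gene, which were left out of the gene counts. A further 439 genes of the Y chromosome and XIST were left out for privacy, which left 55326 genes, and 40550 of these had at least 1 count. Library totals over genes ranged from 1724807 to 6799313 counts, and a floor of 3 counts corresponded to 0.441 to 1.74 CPM (counts-per-million, a count scaled to the library total) in a library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates differed by far more than counting error, with a chi-squared per degree of freedom between 17.6 and 70.3 for the 30 pairs of replicates.

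Counts were normalised by TMM and filtered with filterByExpr (minimum count 10) in edgeR 4.0.16 under R 4.3.3, which left 15568 genes. All 30 libraries were fitted together with 1 mean per population (20 residual degrees of freedom), and contrasts were tested by the edgeR quasi-likelihood F test, which is two-sided. The common biological coefficient of variation was 0.606. Values of p were adjusted by Benjamini-Hochberg over the genes of each comparison, and genes with an adjusted p under 0.05 were called. The 22 comparisons were a test of any difference among the populations, each population against naive, 10 contrasts among non-naive populations, 1 contrast of all non-naive populations against naive, and 1 difference between a pair of contrasts. A contrast of several populations averages the log means of the populations with equal weight, and it can therefore differ from a ratio of mean CPM. Errors of log2 fold changes are standard errors (SE) computed from the F statistic, and errors of CPM are standard deviations (SD) over 3 libraries. Where a population had no counts of a gene, no fitted fold change is given, and bounds were computed with 3 counts over that population.

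The named genes were chosen by a rule, for 7 main comparisons. It takes up to 12 genes with the largest positive and up to 12 with the largest negative log2 fold change among those with an adjusted p under 0.05, at least 10 CPM on the higher side and the same sign in each of the 3 donors. Clone-based or unnamed loci (pseudogenes and antisense transcripts included), receptor and immunoglobulin segments and HLA genes were left out of that choice. Pseudogenes were found by their symbol in GENCODE release 29, so that EMR4P, a pseudogene under an older symbol, was not left out. A fixed panel of T cell genes and the list members with the smallest p are given besides. The 21 gene lists (361 members, of which 2 were absent from the table) were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and with a correlation estimated for each list. Some members belong to more than 1 list, among them MAF (Th2 and Th17), GZMA and GZMK (Th1 and cytotoxic granule), IL2RB (memory and NK cell), GZMH (cytotoxic granule and CD8 T cell), NCR3 (NK cell and gamma-delta or MAIT) and TYROBP and FCER1G (monocyte and NK cell). List medians are given with members absent from a population at their bound where this changes them. The groups, comparisons, tests, lists and the rule for named genes were fixed before the data were examined.

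The alternatives fixed at that time were a donor block, DESeq2 size factors in the edgeR test, the DESeq2 1.42.0 test itself, no filter on low counts, only the compared populations in the fit, an estimated correlation for the lists, and leaving out each library in turn. Where a library is left out, its population keeps 2 libraries and shares the spread of all the others. A pair of alternatives was added after seeing the data. One thinned every library to 1724807 counts. The other left out the 4 libraries with over 2000 CPM of LYZ, S100A8 and S100A9 together or over 200 CPM of GNLY. Tables were prepared with Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1. The tests were also tested on simulated data, in which 100 genes were changed 2-fold and 100 genes 4-fold. The changed genes were drawn from those with a mean of at least 10 CPM, and no donor effect was simulated. The numbers recovered therefore do not hold for genes with lower levels. For Th1 against Th2, edgeR recovered 8 of the 2-fold and 52 of the 4-fold changes with 0 false calls, and DESeq2 recovered 17 and 73 with 19 false calls. For the CCR6 and Th17 groups against other memory, edgeR recovered 56 and 96 with 8 false calls, and DESeq2 70 and 100 with 48. For non-naive against naive, edgeR recovered 34 and 85 with 15 false calls, and DESeq2 44 and 90 with 25.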

Results

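Gene expression was measured by RNA sequencing in 10 populations of T cells sorted from the blood of 3 healthy donors, with 1 library per donor and population and 30 libraries in all. Naive cells have not met antigen, central memory cells recirculate through lymph nodes, and TSCM cells are memory cells that keep many features of naive cells. Helper subsets are told apart at the surface by chemokine receptors, with CXCR3 on Th1 cells, CCR4 on Th2 cells, and CCR6 with CCR4 on Th17 cells. Gene counts per library ranged from 1724807 to 6799313 (median 4365405), and between 15262 and 22335 genes were detected. Mean counts per library (SD, n = 3) were 5434494 ± 897041 in naive, 5157032 ± 696532 in TSCM_CCR4, 4086365 ± 127542 in TSCM_CXCR3, 4582358 ± 1154555 in CM and 4412064 ± 2036275 in CXCR3_CCR4. They were 3064712 ± 846521 in Th1, 3497484 ± 962554 in Th2, 5668989 ± 1182132 in CCR6, 4725603 ± 436493 in Th17 and 3545563 ± 1732403 in Th1_17. Of all reads, 34.9% to 42.5% were counted in genes and 26% to 30.7% were not aligned. Ribosomal protein genes took 17.1% to 34.4% of gene counts and mitochondrially encoded genes 1.12% to 3.75%. Replicates of a population correlated across genes with r between 0.723 and 0.928, where genes are not independent replicates. The first axis of a principal component decomposition of 1000 genes held 16.8% of the variance and the second 13.1%. Deviations from the population mean correlated across genes with a median r of 0.088 between libraries of the same donor and -0.045 between donors. Of 135 same-donor pairs, 129 had an r over 0, and all 30 libraries were on average closest to their own donor. The main fit had no donor term, and a donor block was used as an alternative.

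Of the receptors and regulators of helper subsets, some passed the test of any difference among the 10 populations and some did not. CCR4, CXCR3, CCL5, CCR7, FOXP3 and RORA passed, and CCR6 (adjusted p = 0.148), PTGDR2 (0.147), TBX21 (0.118), GATA3 (0.0506), KLRB1 (0.0587) and EOMES (0.666) did not. CCR4, which guides cells to skin, was at 373 ± 54.2 CPM in Th2 (SD, n = 3), 331 ± 79.6 in Th17, 251 ± 113 in CXCR3_CCR4 and 0.714 ± 0.611 in naive. CXCR3, which guides cells to inflamed tissue, was at 339 ± 46.6 CPM in CXCR3_CCR4, 316 ± 40.6 in Th1_17 and 209 ± 53.1 in Th1. CTSH, a lysosomal protease gene, was at 78.7 ± 28.2 CPM in Th17, 68.5 ± 17.3 in CCR6 and 45.5 ± 27.1 in Th1_17. CCL5, a chemokine of effector cells, was at 676 ± 178 CPM in Th1 and 674 ± 102 in Th1_17, against 13.3 ± 4.35 in Th17. CCR7, which leads cells into lymph nodes, was at 1640 ± 41.3 CPM in naive, 1350 ± 217 in TSCM_CCR4, 1280 ± 251 in TSCM_CXCR3, 927 ± 119 in CM and 487 ± 46.5 in Th1_17. The test of any difference among the populations called 436 of 15568 genes by edgeR. CD4 means were between 119 and 173 CPM in every population, and CD3E means between 110 and 189.

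**Figure D1:**
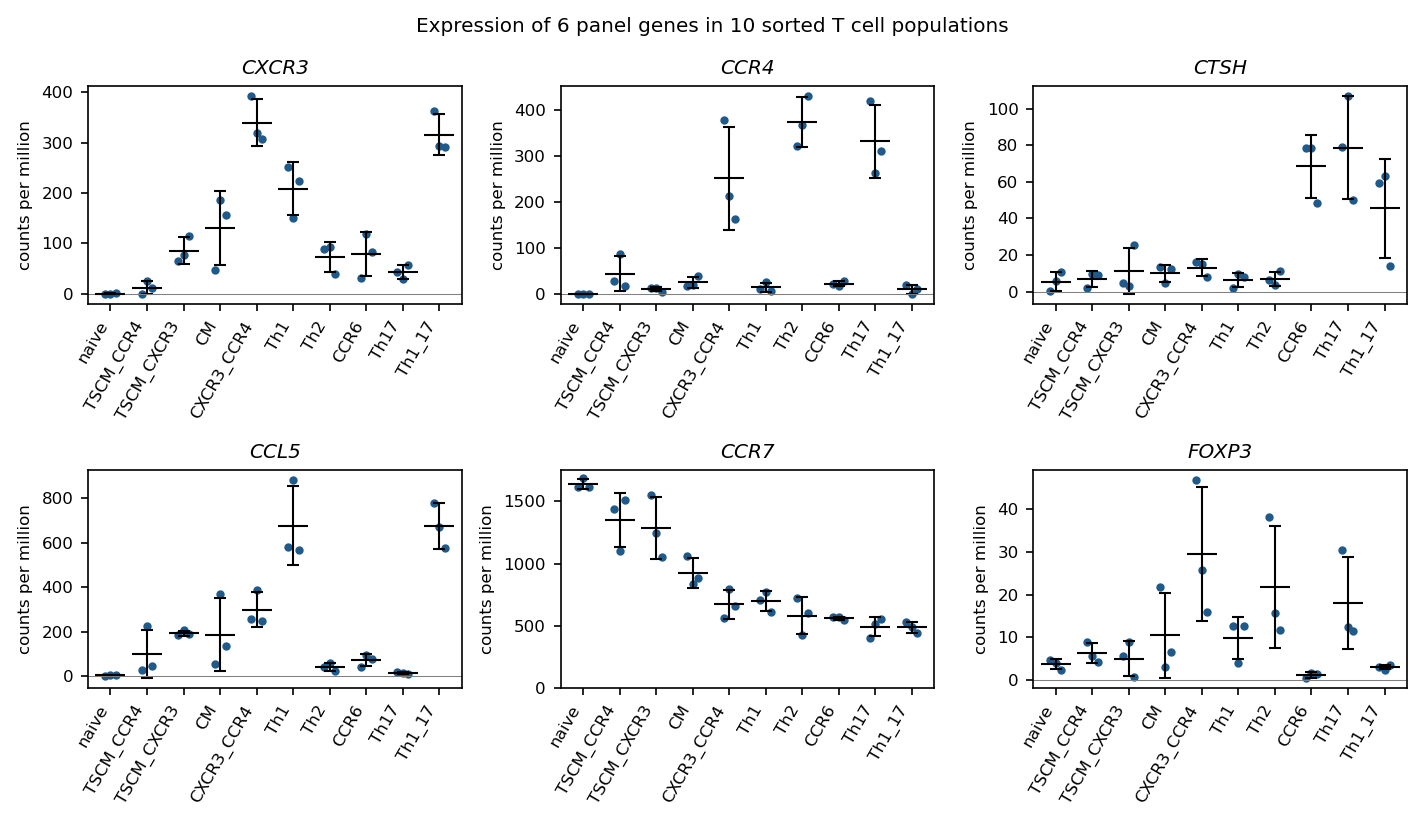
CPM (vertical axis) of CXCR3, CCR4, CTSH, CCL5, CCR7 and FOXP3 in the 10 populations (horizontal axis), with a point per library and the mean and SD of 3 libraries as a dash and bars. CCR4 was at 373 ± 54.2 CPM in Th2 and CTSH at 78.7 ± 28.2 CPM in Th17, and CCR7 was at 1640 ± 41.3 CPM in naive.

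The contrast of the 9 non-naive populations with naive asked which genes go with antigen experience. Non-naive cells had more of the homing receptors CXCR3 (log2 fold change 7.07 ± 0.86 SE, adjusted p = 1.62e-05, 143 against 0.712 CPM) and CCR4 (6.08 ± 0.74, adjusted p = 1.62e-05). Some of these populations were gated on CXCR3 or CCR4, by label or by convention, so that part of these rises may come from the sort. FUT7, the enzyme that builds selectin ligands for entry into tissue, rose by 5.60 ± 0.85 (adjusted p = 0.000171), and CCL5 rose by 5.34 ± 0.67 (adjusted p = 2.25e-05). The death receptor gene FAS was at 31.7 against 2.68 CPM (3.34 ± 0.52, adjusted p = 0.000206), though in TSCM_CCR4 (8.06 CPM) and TSCM_CXCR3 (10.3 CPM) it did not pass against naive (adjusted p = 0.716 and 0.287). The lymph node receptor CCR7 fell by 1.17 on the log2 scale (adjusted p = 1.25e-05, 784 against 1640 CPM). LEF1, a transcription factor of resting T cells, fell by 1.12 (adjusted p = 2.87e-05). NOG, an inhibitor of bone morphogenetic proteins, fell by 3.94 (adjusted p = 2.69e-05), the matrix protease gene MMP28 fell by 4.54 (adjusted p = 2.04e-05) and the keratin gene KRT72 fell by 3.42 (adjusted p = 0.000301).

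edgeR called 220 genes higher and 164 lower in non-naive cells. The genes named by the rule also included IL18RAP, PTGDS, ADAM19, TNFRSF18, ADAM23 and HOPX among the higher, and DACT1, BEND5, TTC24, RNF175, DSC1, TTC28, KRT73, CD8B and EMR4P among the lower. DACT1, TTC24, RNF175, DSC1 and EMR4P had 1 population without counts and BEND5 had 2, and with these at their bounds the log2 fold changes were -4.52, -4.07, -3.93, -3.42, -2.65 and -3.84 in that order. Of the panel, IL2RB (1.99 ± 0.40, adjusted p = 0.00348), RORA (0.91 ± 0.23, adjusted p = 0.0244), GZMK (4.76 ± 1.14, adjusted p = 0.0173), GZMA (3.34 ± 0.66, adjusted p = 0.00339), KLRB1 (4.78 ± 1.19, adjusted p = 0.0239) and S100A4 (2.03 ± 0.30, adjusted p = 0.00013) rose, and TCF7 fell by 0.55 (adjusted p = 0.0295). CD8B was not called without naive replicate 1 (adjusted p = 0.179), nor TNFRSF18 without TSCM_CXCR3 replicate 3 (adjusted p = 1.0). Of the 30 fits without 1 library, GZMK, TCF7 and ADAM23 were called in 27, KLRB1, RORA and IL18RAP in 28, and IL2RB and DSC1 in 29. The count of 384 genes became 206, 198 and 246 without naive replicates 1, 2 and 3.

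Among the lists in that contrast, 18 of 23 measured genes of the memory and effector list rose, 0 fell and 5 did not pass, and 22 rose when adjusted over the list alone. Their median log2 fold change was 1.99 (camera adjusted p = 2.4e-35, and 0.000159 with an estimated correlation). The integrin gene ITGB1 (2.79 ± 0.33, adjusted p = 1.25e-05) was its member with the smallest p. Of 21 naive and quiescent genes, 10 fell, 0 rose and 11 did not pass, and 14 fell adjusted over the list alone. Their median was -0.78 (adjusted p = 2.22e-16, and 9.04e-06 with an estimated correlation). BACH2 (-1.60 ± 0.23) and SATB1 (-1.20 ± 0.17), which encode nuclear factors of quiescent cells, were among those that fell. Th1 genes rose in 9 of 20 (0 fell, 11 did not pass, 12 rose adjusted over the list alone), with a median of 3.26 at the bounds (adjusted p = 0.0128 with an estimated correlation). The Th17 list rose in 4 of 16 genes (0 fell, 12 did not pass, 5 rose adjusted over the list alone), with a median of 1.72 at the bounds (adjusted p = 0.00034 with an estimated correlation). The Th2 list rose in 2 of 9 (0 fell, 7 did not pass, 2 rose adjusted over the list alone), with a median of 2.84 at the bounds (adjusted p = 0.0241 with an estimated correlation). The regulatory T cell list rose in 5 of 14 (0 fell, 9 did not pass, 8 rose adjusted over the list alone), with a median of 2.16 (adjusted p = 0.00034 with an estimated correlation). TNFRSF4 (4.12 ± 0.59), IL2RA (2.21 ± 0.34) and TIGIT (2.45 ± 0.34) were among them. Glycolysis genes rose in 2 of 16, TPI1 (0.75 ± 0.16, adjusted p = 0.0083) and PKM (0.74 ± 0.19, adjusted p = 0.0333). In this list 0 fell and 14 did not pass, and 6 rose adjusted over the list alone (median 0.42, adjusted p = 0.0128 with an estimated correlation).

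The remaining lists were not called with an estimated correlation in that contrast. Follicular helper genes rose in 1 of 11 (CXCR5, median 0.45, adjusted p = 0.0247, and 0.0588 with an estimated correlation). Cytotoxic granule genes rose in 3 of 14 (median 1.59, adjusted p = 0.00146, and 0.253 with an estimated correlation) and 4 rose adjusted over the list alone. Immediate early and NF-kB genes rose in 2 of 19 (JUNB and PPP1R15A), 7 adjusted over the list alone, with a median of 1.21 (adjusted p = 2.43e-05, and 0.195 with an estimated correlation). Ribosomal protein genes fell in 1 of 38 (RPS14), 7 adjusted over the list alone, with a median of -0.24 (adjusted p = 0.000651, and 0.396 with an estimated correlation). No gene passed in the interferon response (20 genes, median 0.22, adjusted p = 0.101), cell cycle (19, 0.13, 0.114), oxidative phosphorylation (24, 0.01, 0.164) and mitochondrially encoded lists (13, 0.10, 0.0493, and 0.434 with an estimated correlation). The mitochondrially encoded list changed direction without naive replicate 2 (camera adjusted p = 0.481). Adjusted over the list alone, 2 cell cycle genes and 1 oxidative phosphorylation gene rose. Markers of other blood cells were present beside these changes. Monocyte genes had a median of 2.06 in 13 genes, with none passing (adjusted p = 0.00838, and 0.434 with an estimated correlation). The NK cell list (6 genes, 1 rose) had a median of 1.56 (adjusted p = 0.0203, and 0.195 with an estimated correlation), and the gamma-delta or MAIT list (7 genes, none passing) of 1.22 (adjusted p = 0.0203, and 0.122 with an estimated correlation). In the CD8 T cell list 2 of 4 genes fell (adjusted p = 0.0475 downward, and 0.244 with an estimated correlation), and its median of -0.09 at the bounds and mean of 0.05 differed in sign. The B cell list (9 genes, median 0.49 at the bounds, adjusted p = 0.245) and the platelet or red cell list (8 genes, 0.02, 0.224) were not called.

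Each non-naive population was also set against naive, which asked how far each lies from the naive state. By edgeR, 288 genes were higher and 142 lower in Th1_17, 300 and 111 in Th17, 240 and 81 in CXCR3_CCR4, 220 and 79 in Th2, 210 and 49 in CCR6, 140 and 25 in Th1 and 85 and 4 in CM. The order of these populations depended on the fit. Without the 4 libraries with monocyte or cytotoxic transcripts the count for Th1_17 was 310, against 476 for Th17, 400 for CXCR3_CCR4 and 341 for Th2. The TSCM populations had the fewest genes. TSCM_CCR4 differed in 2 genes, the receptor of its gate CCR4 (5.95 ± 0.79, adjusted p = 0.000543, 44.8 against 0.714 CPM) and CCL5 (4.87 ± 0.71, adjusted p = 0.00168, 99.8 CPM), both higher. Replicate 2, a library with cytotoxic transcripts, carried much of both means. Without it CCR4 was at 23.5 CPM (5.01 ± 0.73, adjusted p = 0.00401) and CCL5 at 37.1 CPM (3.43 ± 0.59, adjusted p = 0.0271). The count for TSCM_CCR4 also depended on the fit, with 6 genes with a donor block, 23 by DESeq2 and none with only the compared populations. TSCM_CXCR3 differed in 22 genes, all higher. Among them were the receptor of its gate CXCR3 (6.90 ± 0.91, adjusted p = 0.000251, 85.9 against 0.712 CPM), CCL5 (5.83 ± 0.73, adjusted p = 0.000217), ITGB1 (2.13 ± 0.36, adjusted p = 0.0104) and CCR4 (3.91 ± 0.80, adjusted p = 0.0421). Others of the 22 were NCF4, PLEK, MYO1F and CST7, the last of which is on the cytotoxic granule list. The genes of both TSCM populations were chosen after their values were seen. Memory and effector genes had a median of 1.03 in TSCM_CXCR3 (2 rose, 16 adjusted over the list alone, adjusted p = 0.0322 with an estimated correlation) and 0.59 in TSCM_CCR4 (6 adjusted over the list alone, adjusted p = 3.34e-05, and 0.215 with an estimated correlation). Beside these, the monocyte list had a median of 4.30 in TSCM_CXCR3 (adjusted p = 1.58e-07, and 0.128 with an estimated correlation), and the platelet or red cell list 2.81 in TSCM_CCR4 (adjusted p = 2.42e-08, and 0.0613 with an estimated correlation). Replicate 3 of TSCM_CXCR3 was high in monocyte transcripts, and without it 4 genes were called. The memory and effector list of TSCM_CXCR3 against naive was not tested without that library, so a part of its rise from other cells stays open.

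Leaving out 1 library, of naive or of the population itself, lowered many of these counts. Without naive replicates 1, 2 and 3 the counts became 252, 253 and 274 for Th1_17, 264, 225 and 249 for Th17, 205, 155 and 194 for CXCR3_CCR4, and 92, 89 and 106 for Th1. Without naive replicates 1 and 2 they became 177 and 177 for Th2, 35 and 39 for CM, and 3 and 3 for TSCM_CXCR3. The count for CCR6 became 166 without naive replicate 2, and that for TSCM_CCR4 became 4 without naive replicate 1. Of the populations' own libraries, the count became 284 and 280 without Th1_17 replicates 1 and 2, 250 and 234 without Th17 replicates 1 and 2, 184 without CXCR3_CCR4 replicate 1 and 172 without CCR6 replicate 2. It became 44 and 59 without CM replicates 2 and 3, 4 without TSCM_CXCR3 replicate 3, and 10 without TSCM_CCR4 replicate 1.

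**Figure D2:**
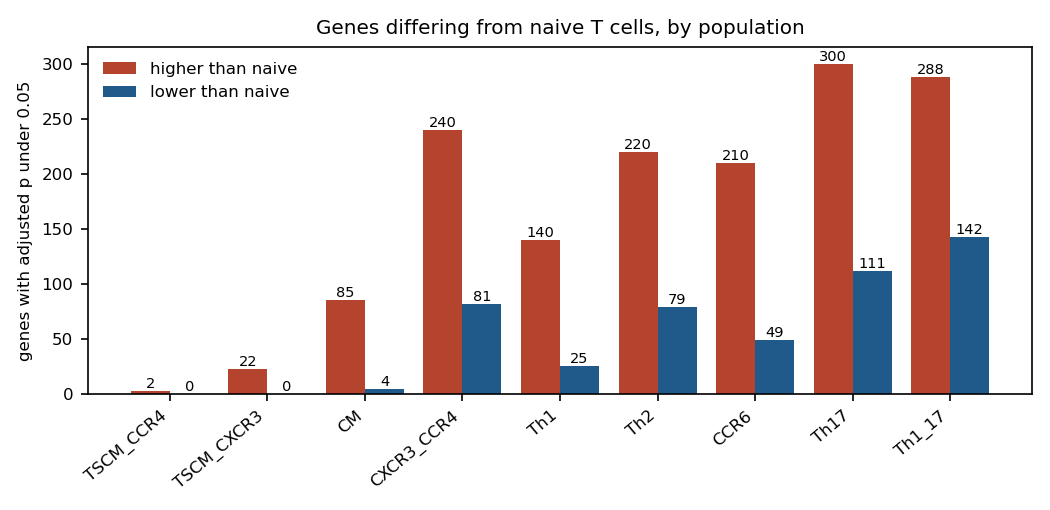
Number of genes with an adjusted p under 0.05 by edgeR (vertical axis) in each of 9 populations against naive (horizontal axis), with bars for genes higher and lower than naive. Th1_17 had 288 higher and 142 lower, and TSCM_CCR4 had 2 higher and 0 lower.

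CM cells were set against both TSCM populations to find the genes that go with the later memory stage. The TSCM gates were labelled with CCR4 or CXCR3, whereas the CM column headings carry NEG. Memory stage and receptor gate therefore cannot be told apart in this contrast. CM had more of the inhibitory receptor TIGIT (2.80 ± 0.31, adjusted p = 1.2e-05, 120 against 17.8 CPM) and of CXCR5 (2.94 ± 0.36, adjusted p = 6.55e-05, 48.7 against 6.38 CPM), the receptor that leads helper cells to B cell follicles. ST8SIA1, which encodes the sialyltransferase that makes ganglioside GD3, rose by 2.77 ± 0.47 (adjusted p = 0.00955), and MAF, a transcription factor of several helper subsets, by 1.94 ± 0.36 (adjusted p = 0.0246). The kinase gene PASK (1.22 ± 0.23, adjusted p = 0.0326), GLCCI1 (1.57 ± 0.30, adjusted p = 0.0326), TRADD, an adaptor gene of tumour necrosis factor receptors (1.20 ± 0.21, adjusted p = 0.0146), and RILPL2 (1.07 ± 0.21, adjusted p = 0.0391) were the other genes named by the rule. edgeR called 10 genes, all higher in CM, and 30 with a donor block, which included these 10. The calls of TIGIT, CXCR5 and ST8SIA1 held without any 1 of the 9 libraries. TRADD was called in 7 of these 9 fits, MAF in 4, and PASK, GLCCI1 and RILPL2 in 2 each. The count became 5 without CM replicate 3, 4 without TSCM_CCR4 replicate 1, and 19 without TSCM_CXCR3 replicate 3.

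In this comparison the naive list was lower in CM in 19 of 21 genes, with none passing alone (median -0.18, adjusted p = 0.00173 with an estimated correlation). The memory list was higher (0 of 23 rose, 7 adjusted over the list alone, median 0.54, adjusted p = 0.00825 with an estimated correlation). Regulatory T cell genes were higher (1 of 14 rose, 4 adjusted over the list alone, median 1.03, adjusted p = 0.00173 with an estimated correlation), as were follicular helper genes (1 of 11 rose, median 0.11, adjusted p = 0.0144 with an estimated correlation). The platelet or red cell list was lower in CM (0 of 8 fell, 8 adjusted over the list alone, median -3.06, adjusted p = 0.0144 with an estimated correlation), with the platelet factor gene PF4 at 11.6 against 175 CPM. TSCM_CCR4 replicate 2 was high in these transcripts, and without it the median was -2.53 (adjusted p = 0.0102 with an estimated correlation). Called only with the preset correlation were Th1 (median 0.92, adjusted p = 3.79e-06, and 0.0776 with an estimated correlation), Th2 (0.57 at the bounds, 0.0144 and 0.0725) and Th17 (0.65 at the bounds, 0.0103 and 0.0815). So were, as lower, oxidative phosphorylation (-0.37, 0.000247 and 0.16), ribosomal protein (-0.43, 2.97e-13 and 0.0815), mitochondrially encoded (-0.53, 0.000124 and 0.148), B cell (-1.25, 0.00878 and 0.148) and monocyte genes (-0.71, 0.0291 and 0.584). Without the 4 libraries with monocyte or cytotoxic transcripts the monocyte list changed direction and was not called. Immediate early genes had a median of 0.21 and a mean of -0.16 (adjusted p = 0.00624 upward, and 0.403 with an estimated correlation).

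TSCM_CXCR3 and TSCM_CCR4 were compared to ask whether helper polarity is already present at the TSCM stage. The sorting receptors lay on the sides of their gates, with CXCR3 at 85.9 ± 25.9 CPM in TSCM_CXCR3 and 12 ± 12.7 in TSCM_CCR4 (SD, n = 3), and CCR4 at 10.8 ± 4.44 and 44.8 ± 37.6 CPM. Neither passed over all genes, and CXCR3 had a log2 fold change of 2.87 ± 0.69 (adjusted p = 0.458, and 0.0053 when adjusted over the list alone). By edgeR 0 genes were called, with 950 at an unadjusted p under 0.05, and DESeq2 called 13. Th1 genes were higher in TSCM_CXCR3 with the preset correlation (0 of 20 rose, 4 adjusted over the list alone, median 1.07, adjusted p = 2.76e-06, and 0.348 with an estimated correlation). The Th2 list was not called (median 0.15 at the bounds, adjusted p = 0.77). No list was called with an estimated correlation. With the preset correlation, memory (median 0.39, adjusted p = 0.000712), cytotoxic granule (0.36, 0.0209), immediate early (1.15, 0.00034) and monocyte genes (2.37, 0.00599) were higher. Oxidative phosphorylation (-0.44, 0.00115), ribosomal protein (-0.33, 0.00233), mitochondrially encoded (-0.51, 0.0286) and platelet or red cell genes (-1.54, 0.00233) were lower. These 8 lists had an adjusted p of 0.472 with an estimated correlation. Without TSCM_CXCR3 replicate 3 the cytotoxic granule, immediate early and monocyte lists changed direction (adjusted p = 0.968, 0.926 and 0.949). Ribosomal protein genes changed direction without TSCM_CCR4 replicate 2 (adjusted p = 0.371). Without the 4 libraries with monocyte or cytotoxic transcripts they were called as higher (adjusted p = 0.000141), and oxidative phosphorylation genes changed direction (adjusted p = 0.735). Without TSCM_CCR4 replicate 3, 1 gene was called. The regulatory and follicular helper lists had medians of 0.44 at the bounds and 0.16 and tests that pointed downward (adjusted p = 0.86 and 0.95).

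Th1 against Th2 is the classical pair of opposed helper fates. Th1 cells had more CCL5, which draws effector cells to inflamed tissue (4.08 ± 0.65, adjusted p = 0.0073, 676 against 39.9 CPM), and fewer transcripts of the skin-homing receptor CCR4 (-4.60 ± 0.64, adjusted p = 0.00145, 15 against 373 CPM). These were the 2 genes called by edgeR. CCR4 is a receptor commonly used to sort Th2 cells, so that its difference may come from the gates alone. The master regulators of the fates did not pass, with TBX21 at 2.56 ± 1.02 (adjusted p = 0.729) and GATA3 at -0.98 ± 0.35 (adjusted p = 0.678, 180 against 355 CPM). CXCR3 did not pass either (1.52 ± 0.63, adjusted p = 0.762). GATA3 was nevertheless higher in Th2 in each of the 3 donors (234, 316 and 514 CPM, against 110, 203 and 228 in Th1). TBX21 was higher in Th1 in each (2.12, 12.6 and 5.82 against 0, 1.25 and 2.15 CPM). The fit had no donor term, and these results do not show that the levels are equal. The Th2 list, which includes CCR4 itself, was lower in Th1 in 9 of 9 genes (1 fell, 4 adjusted over the list alone, median -2.27, adjusted p = 3.56e-05 with an estimated correlation). Regulatory T cell genes were lower in 13 of 14 (0 fell, 4 adjusted over the list alone, median -1.22, adjusted p = 0.000103 with an estimated correlation). Th1 genes (1 of 20 rose, median 1.07, adjusted p = 1.36e-07, and 0.0615 with an estimated correlation), naive genes (0.26, 0.00467 and 0.0615) and memory genes (-0.47, 8.4e-06 and 0.191) were called only with the preset correlation. So were cytotoxic granule genes (1.15, 0.00467 and 0.538), immediate early genes (0.45 at the bounds, 0.0115 and 0.659) and CD8 T cell genes (2.21, 0.0343 and 0.312). CCL5 was called in 4 of the 6 fits without 1 library, with its highest adjusted p of 0.0947 without Th2 replicate 1, and CCR4 in all 6.

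The CCR6 and Th17 groups (CCR6, Th17 and Th1_17) were set against the other memory populations (CM, CXCR3_CCR4, Th1 and Th2) to find genes that go with the Th17 lineage. LTK, a receptor tyrosine kinase, rose by 4.71 ± 0.57 (adjusted p = 9.63e-05, 75.9 against 4.49 CPM), the phosphatase gene PTPN13 by 3.88 ± 0.55 (adjusted p = 0.000316) and the lysosomal protease gene CTSH by 2.82 ± 0.43 (adjusted p = 0.000552). ABCB1, a drug efflux pump, rose by 2.85 ± 0.57 (adjusted p = 0.0107, 45.5 against 7.48 CPM), and the nuclear receptor gene RORA by 0.82 ± 0.15 (adjusted p = 0.00573). TIGIT fell by 1.92 on the log2 scale (adjusted p = 1.29e-05, 34.3 against 107 CPM), and ST8SIA1 fell by 2.17 (adjusted p = 0.000417). FOXP3, the regulator of regulatory T cells, fell by 1.96 (adjusted p = 0.0189, 7.43 against 17.9 CPM). It was low in CCR6 (1.18 ± 0.66 CPM) and Th1_17 (3.05 ± 0.51) but not in Th17 itself (18.1 ± 10.7), against 10.5 ± 9.92 in CM and 9.81 ± 4.92 in Th1. The giant muscle protein gene TTN fell by 2.04 (adjusted p = 0.000292).

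edgeR called 75 genes higher and 35 lower in this contrast. The rule also named ELOVL4, COL5A3, IL18RAP, AGPAT4, ALOX5, FRY and PDE4D among the higher genes and FCRL3, SESN3, CPNE2, PLXDC1, SCML1, FHIT, PLEKHG2 and RNF214 among the lower. Of the panel, CCR7 (-0.47 ± 0.11, adjusted p = 0.0395) and LEF1 (-0.53 ± 0.12, adjusted p = 0.0277) fell. Without the low-count filter, in thinned libraries and without the 4 libraries with monocyte or cytotoxic transcripts they kept their direction but were not called. In the 21 fits without 1 library, CCR7 was called in 4 (log2 fold change -0.50 to -0.41) and LEF1 in 10 (-0.57 to -0.47). Th17 genes were higher in 16 of 16 (10 rose, 0 fell, 6 did not pass, and 14 rose adjusted over the list alone). Their median was 2.48 at the bounds (adjusted p = 2.12e-37, and 2.09e-08 with an estimated correlation). Cell cycle genes were lower (0 of 19 fell, 5 adjusted over the list alone, median -0.92, adjusted p = 0.0146 with an estimated correlation). Follicular helper genes were lower as well (1 of 11 fell, CXCR5 with -1.0 ± 0.24, 3 adjusted over the list alone, median -0.37, adjusted p = 0.0177 with an estimated correlation). Memory genes (3 of 23 rose, median 0.46, adjusted p = 2.01e-08, and 0.0785 with an estimated correlation), naive genes (1 of 21 rose and 5 fell, median -0.27, adjusted p = 0.013, and 0.0824 with an estimated correlation) and ribosomal protein genes (0.20, 1.1e-05 and 0.354) were called only with the preset correlation. The count of 110 became 68 without CCR6 replicate 2 and 65 without Th17 replicate 2. With a donor block it was 170. Of the 21 fits, ALOX5 and FCRL3 were called in 4, IL18RAP in 11, CPNE2 in 12, FHIT in 14, SCML1 in 15, PLEKHG2 and FOXP3 in 17 and COL5A3 in 20.

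The Th1 and CXCR3 groups (CXCR3_CCR4, Th1 and Th1_17) were compared with CCR6, CM, Th17 and Th2. CCL5 rose by 3.32 ± 0.32 (adjusted p = 1.11e-06, 549 against 77.8 CPM) and the sorting receptor CXCR3 by 1.90 ± 0.34 (adjusted p = 0.0252, 288 against 81.3 CPM). YARS, which loads tyrosine onto its transfer RNA, rose by 0.87 ± 0.13 (adjusted p = 0.00368, 134 against 75.2 CPM). These were the 3 genes called by edgeR, and the granzyme genes GZMK (2.20 ± 0.54, adjusted p = 0.192) and GZMA (1.39 ± 0.35, adjusted p = 0.212) did not pass. Th1 genes, which include CXCR3 itself, were higher (2 of 20 rose, 8 adjusted over the list alone, median 1.17, adjusted p = 5.91e-17, and 0.00652 with an estimated correlation). The Th2 list was lower (0 of 9 fell, 2 adjusted over the list alone, median -0.82 at the bounds, adjusted p = 0.00839 with an estimated correlation), as was the regulatory T cell list (median -0.41, adjusted p = 0.0334 with an estimated correlation). Cell cycle genes were higher (2 of 19 adjusted over the list alone, median 0.32, adjusted p = 0.0385 with an estimated correlation). Cytotoxic granule genes (5 of 14 adjusted over the list alone, median 1.25, adjusted p = 4.49e-08, and 0.0722 with an estimated correlation), Th17 genes (-0.21 at the bounds, 0.0029 and 0.0525), immediate early genes (0.14 at the bounds, 0.0231 and 0.637) and CD8 T cell genes (1.25 at the bounds, 0.0343 and 0.219) were called only with the preset correlation. Without the low-count filter the cell cycle and immediate early lists pointed downward (adjusted p = 0.75 and 0.242). CXCR3 was called in 9 of 21 fits without 1 library, with its highest adjusted p of 0.0921 without Th17 replicate 2. The count became 6, 5 and 5 without Th1 replicate 2, Th1_17 replicate 3 and Th2 replicate 3.

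The Th2 and CCR4 groups (CXCR3_CCR4, Th2 and Th17) were compared with CCR6, CM, Th1 and Th1_17. CCR4 rose by 4.14 ± 0.32 (adjusted p = 5.77e-09, 319 against 18.6 CPM). The groups were pooled by this receptor, by label or by convention, so that its rise is no independent result. CCR10, another receptor for homing to skin, rose by 5.55 ± 0.71 (adjusted p = 0.000163, 29.1 against 0.642 CPM). FOXP3 rose by 2.34 ± 0.40 (adjusted p = 0.00696, 23.1 against 6.15 CPM), together with the inhibitory receptor TIGIT (1.08 ± 0.20, adjusted p = 0.0115) and IL2RA, the high-affinity chain of the interleukin-2 receptor (1.04 ± 0.20, adjusted p = 0.0173). LMNA, a nuclear lamina gene of memory cells, rose by 2.80 ± 0.54 (adjusted p = 0.018), and CCL5 fell by 2.37 on the log2 scale (adjusted p = 0.000768, 117 against 402 CPM). LRRC32, which holds latent TGF-beta on regulatory T cells, was at 5.40 against 0.126 CPM (adjusted p = 0.0238), and the interleukin-25 receptor gene IL17RB at 4.69 against 0.0497 CPM (adjusted p = 0.0111). CTLA4 did not pass (1.15 ± 0.26, adjusted p = 0.0579).

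edgeR called 24 genes higher and 11 lower in this contrast. The rule also named PTPLA, CNTNAP1, TOX2, MEOX1, CPNE2, USP28, TTN and LGALS1 among the higher genes and FAM26F, ZSCAN18, RNF157, DPP4 and NELL2 among the lower. Regulatory T cell genes, which include the homing receptor CCR10, were higher in 14 of 14 (6 rose, 0 fell, 8 did not pass, and 10 rose adjusted over the list alone). Their median was 1.12 at the bounds (adjusted p = 3.87e-26, and 3.88e-07 with an estimated correlation). Th2 genes, which include CCR4 itself, were higher in 8 of 9 (2 rose, 4 adjusted over the list alone, median 1.45, adjusted p = 8.09e-06 with an estimated correlation). Memory genes (2 of 23 rose, 7 adjusted over the list alone, median 0.38, adjusted p = 0.0101 with an estimated correlation), follicular helper genes (1 of 11 rose, 2 adjusted over the list alone, 0.21 at the bounds, 0.0115 with an estimated correlation) and cell cycle genes (0 of 19 rose, 3 adjusted over the list alone, 0.67, 0.00638 with an estimated correlation) were higher. Naive genes were lower (1 of 21 fell, 5 adjusted over the list alone, -0.23, 0.00395 with an estimated correlation). Th1 (median -0.42, adjusted p = 1.88e-05, and 0.105 with an estimated correlation), cytotoxic granule (-0.86, 0.00144 and 0.363), immediate early (-0.23, 0.000749 and 0.375), ribosomal protein (-0.15, 2.76e-05 and 0.375) and monocyte genes (-1.33, 0.0156 and 0.581) were called as lower only with the preset correlation. Of the 21 fits without 1 library, DPP4 was called in 4, NELL2 and USP28 in 5, LGALS1 in 9, PTPLA in 10, CNTNAP1 in 12, FAM26F in 13, TOX2 in 14, ZSCAN18 in 19, and LMNA and MEOX1 in 20. The count of 35 became 19 without CCR6 replicate 2, 17 without CXCR3_CCR4 replicate 1, 20 without Th1_17 replicate 3, 14 without Th17 replicate 1 and 70 with a donor block.

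**Figure D3:**
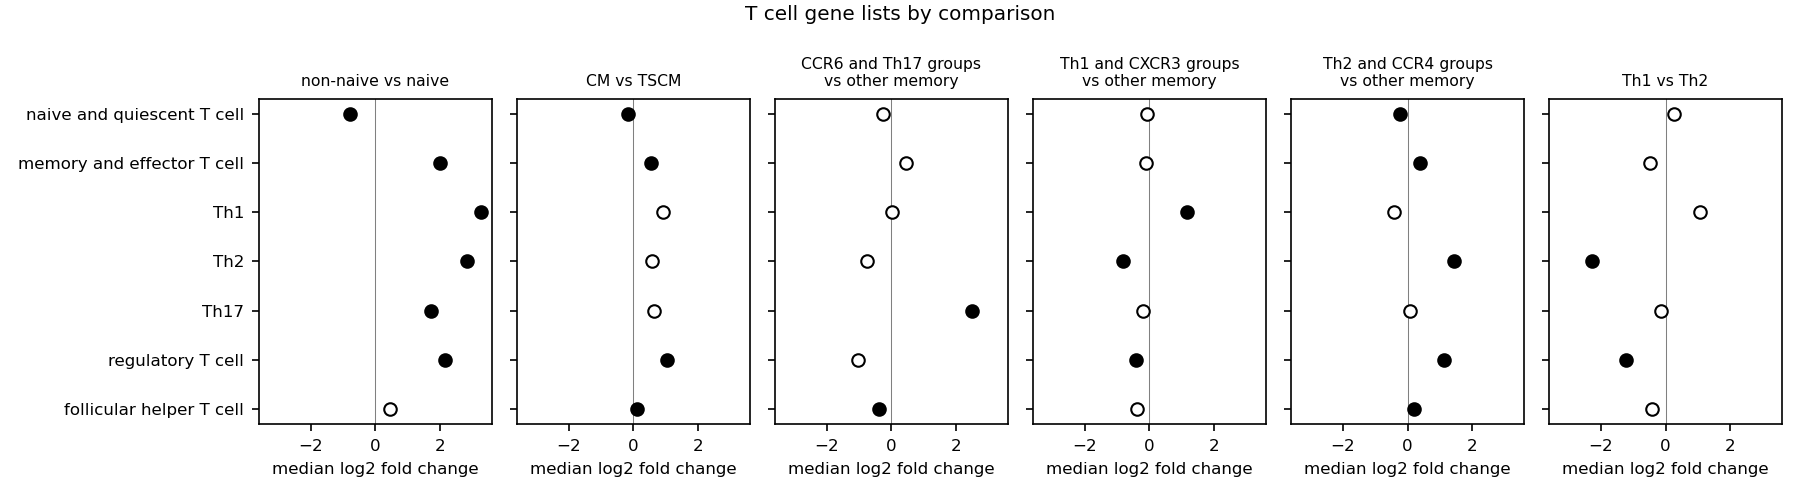
Median log2 fold change (horizontal axis) of 7 T cell gene lists (vertical axis) in 6 comparisons, with members absent from a population at their bound. Filled points had a camera adjusted p under 0.05 with an estimated correlation, as the Th17 list with 2.48 in the CCR6 and Th17 groups, and open points did not.

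Comparisons between single memory populations called few genes, which were chosen here after their values were seen. There were 6 for Th17 against Th1, 3 for Th1_17 against both and 2 for CCR6 against CM. With a donor block these counts were 13, 3 and 8. Th17 cells had less CCL5 than Th1 cells (-5.67 ± 0.70, adjusted p = 0.000163) and more CCR4 (4.43 ± 0.64, adjusted p = 0.00125). They also had more of the clock repressor NR1D1 (3.05 ± 0.47, adjusted p = 0.0028, 72.0 against 8.66 CPM), PTPN13 (7.08 ± 1.34, adjusted p = 0.0341) and ANK1 (3.75 ± 0.70, adjusted p = 0.0341), and PLXDC1 fell by 2.24 (adjusted p = 0.0341). Th17 genes were higher in Th17 than in Th1 (10 adjusted over the list alone, median 2.24 at the bounds, adjusted p = 1.76e-06 with an estimated correlation), as were regulatory T cell (2.05, 6.02e-05), Th2 (1.30, 0.000431) and memory genes (0.80, 0.00963). Naive genes were lower there (-0.46, 0.00333 with an estimated correlation). Th1_17 cells, which combine features of both fates, had more CCL5 (2.83 ± 0.48, adjusted p = 0.0171) and fewer transcripts of CXCR5 (-2.53 ± 0.44, adjusted p = 0.0171) and TIGIT (-2.31 ± 0.36, adjusted p = 0.0125) than the mean of Th1 and Th17. CCL5 was at 674 CPM in Th1_17, 676 in Th1 and 13.3 in Th17, and so was not higher than in Th1. The Th1 list (0.90 at the bounds, adjusted p = 0.0355 with an estimated correlation) and the Th17 list (0.90, 0.0266) were higher in Th1_17, and follicular helper genes lower (-0.39, 0.0266). Th1 genes at the level of Th1 and Th17 genes at that of Th17 would also exceed such a mean. These list results therefore show no excess over Th1 or Th17 alone. CCR6 cells had less TIGIT (-2.39 ± 0.38, adjusted p = 0.0149, 22.8 against 120 CPM) and TTN (-3.04 ± 0.53, adjusted p = 0.0319) than CM. They had more of the Th17 list (10 adjusted over the list alone, median 2.94 at the bounds, adjusted p = 3.14e-07 with an estimated correlation) and of the memory list (6 adjusted over the list alone, 0.76, 0.0363).

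CXCR3_CCR4 cells, which carry the receptors of both Th1 and Th2 cells, were compared with the mean of Th1 and Th2. By edgeR 0 genes were called, with 809 at an unadjusted p under 0.05, and DESeq2 called 0. Regulatory T cell genes were higher (1 adjusted over the list alone, median 1.06, adjusted p = 4.88e-07, and 0.00327 with an estimated correlation), as were cell cycle genes (0.88, 1.85e-07 and 0.00327). Without 1 library, the counts for Th17 against Th1 became 2 without Th1 replicate 3 and 3 each without Th17 replicates 1 and 2. For Th1_17 the count became 5 without Th1_17 replicate 1, 0 without Th1_17 replicate 3, and 1 each without Th1 replicates 1 and 2, Th1_17 replicate 2 and Th17 replicates 2 and 3. For CCR6 against CM it became 1 without CCR6 replicate 1, and 0 without CCR6 replicates 2 and 3 and without CM replicates 1 and 3.

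The last comparison asked whether the difference between Th1 and Th2 differs from that between TSCM_CXCR3 and TSCM_CCR4. By edgeR 0 genes were called, with 960 at an unadjusted p under 0.05, and DESeq2 called 17. Without TSCM_CCR4 replicate 2, 1 gene was called. The Th2 list differed between the pairs (median difference -2.57, adjusted p = 2.04e-06, and 0.00121 with an estimated correlation), with a median of -2.27 for Th1 against Th2 and 0.15 at the bounds for the TSCM pair. Regulatory T cell genes differed as well (-1.69, or -1.93 at the bounds, adjusted p = 5.52e-05, and 0.0136 with an estimated correlation), with -1.22 for Th1 against Th2 and 0.44 at the bounds for the TSCM pair. With an estimated correlation this difference was not called without TSCM_CXCR3 replicate 3 (adjusted p = 0.0626) or Th1 replicate 2 (adjusted p = 0.0645).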

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

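The fits on thinned libraries and without 4 libraries and the comparison of IKZF2 and RTKN2 with FOXP3 are tests chosen only after the result was seen. For 6 of 21 lists, the difference between Th1 and Th2 differed from that between TSCM_CXCR3 and TSCM_CCR4 by camera with the preset correlation. The Th2 list differed by a median of -2.57 on the log2 scale (adjusted p = 2.04e-06, and 0.00121 with an estimated correlation), and was called in all 12 fits without 1 library with either correlation. Its size at the bounds varied, with -1.53 in thinned libraries (adjusted p = 0.00142), -3.29 without Th1 replicate 2 and -1.86 without TSCM_CCR4 replicate 3. The regulatory T cell list differed by -1.93 at the bounds (adjusted p = 5.52e-05, and 0.0136 with an estimated correlation), and with an estimated correlation it was called in 10 of 12 such fits, the exceptions being those without TSCM_CXCR3 replicate 3 (0.0626) and Th1 replicate 2 (0.0645). Without the 4 libraries with transcripts of other cells its difference was -1.26 at the bounds (adjusted p = 0.00237, and 0.0664 with an estimated correlation). The naive list differed by 0.43 (adjusted p = 0.0045, and 0.0578 with an estimated correlation) and the memory list by -0.72 (8.66e-09 and 0.0579). With a donor block both were called with an estimated correlation (0.0384 for each), as were the naive list in thinned libraries (0.0376) and the memory list without the 4 libraries (0.0381), so that these calls depended on the fit.

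The mitochondrially encoded list differed by 0.50 (adjusted p = 0.0411, and 0.74 with an estimated correlation), with 0.22 for Th1 against Th2 and -0.51 for the TSCM pair. It was not called with the preset correlation in 8 of 12 fits without 1 library, nor without the 4 libraries (adjusted p = 0.545). The CD8 T cell list, which has 4 genes, differed by 3.90 (adjusted p = 0.0123, and 0.201 with an estimated correlation), with 2.21 for Th1 against Th2 and -1.69 for the TSCM pair. Without TSCM_CCR4 replicate 2, which had 493 CPM of GNLY against a median of 17.9 CPM in 26 other libraries, its difference was 0.52 (adjusted p = 0.202), and in thinned libraries it was not called (adjusted p = 0.055). With the preset correlation it was also not called without TSCM_CXCR3 replicate 1 (0.0664), Th1 replicates 2 (0.082) and 3 (0.0768) or Th2 replicate 3 (0.0577). In these fits its difference at the bounds stayed between 2.76 and 3.57.

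Regulatory T cell genes were higher in the Th2 and CCR4 groups, and regulatory T cells among the cells of the CCR4 gates are a candidate explanation, since no marker that would remove them is given in the labels. Library size alone is argued against, since the median log2 fold change of the list at the bounds was 1.21 with every library at equal depth and 1.12 at full depth. A single library as the only cause is argued against as well, since the lowest median at the bounds over the fits without 1 memory library was 1.07. Cells of that type would raise IKZF2 and RTKN2 about as much as FOXP3, and the larger of the differences from FOXP3 was 0.55 standard errors, which goes with that explanation but is a weak test at these errors. A higher level of these genes in CCR4-positive helper cells themselves stays open and was not tested.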

How the results depend on the processing

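The fits on thinned libraries and without the 4 libraries with transcripts of other cells were chosen only after the data were seen. DESeq2 size factors in the edgeR test moved the median log2 fold change by at most 0.02, and each count of genes stayed within 1.5 times. Of 93 results for named genes, none reversed, and 93 were called with a donor block, 93 by DESeq2, 89 with its size factors, 91 without the low-count filter, 87 of thinned libraries, 86 without the 4 libraries and 5 of 10 with only the compared populations, as were 1866 of 2133 without 1 library. DESeq2 called more genes. It called 1273 for any difference among all 10 populations. It called 648 for non-naive, 566 for CCR6, 194 for CM, 662 for CXCR3_CCR4, 312 for Th1, 855 for Th1_17, 738 for Th17, 629 for Th2, 23 for TSCM_CCR4 and 106 for TSCM_CXCR3 against naive. There were 54 for CM against TSCM, 13 for the TSCM pair, 32 for Th1 against Th2, 58 for Th17 against Th1, 64 for Th1_17 against both, 27 for CCR6 against CM. There were 251, 53 and 125 for the CCR6 and Th17, Th1 and CXCR3, and Th2 and CCR4 groups, and 17 for the difference of contrasts. In the same order, no low-count filter gave 3395, 1480, 519, 247, 545, 321, 679, 594, 495, 140 and 239. It then gave 167, 87, 58, 93, 155 and 46, then 321, 132 and 291, and 27. It gave 23 for CXCR3_CCR4 against Th1 and Th2. A donor block gave 170 for the CCR6 and Th17, 6 for the Th1 and CXCR3 and 70 for the Th2 and CCR4 groups, 8 for CCR6 against CM, 30 for CM against TSCM, 13 for Th17 against Th1 and 6 for TSCM_CCR4 against naive. With only the compared populations in the fit, which leaves fewer samples, there were 13 for CCR6 against CM, 5 for CM against TSCM, 5 for Th1 against Th2, and 28 for Th17 against Th1. Against naive there were 52 for CM, 209 for Th1_17, 676 for Th17, 133 for Th2, 0 for TSCM_CCR4 (edgeR, with 2 in the joint fit and 23 by DESeq2) and 4 for TSCM_CXCR3. Thinned libraries gave 8 for CCR6 against CM, 7 for Th1_17 against both, 4 for TSCM_CCR4 and 14 for TSCM_CXCR3. Leaving out the 4 libraries gave 27 for CM against TSCM, 4 for Th1 against Th2, 6 for Th1_17 against both, 55 for the Th2 and CCR4 groups and 8 for TSCM_CXCR3. Of the 384 genes called for non-naive against naive, 374 were also called with a donor block, 342 by DESeq2 and 348 without the 4 libraries.

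Of 72 calls of lists in the main comparisons, 27 held with an estimated correlation, 72 with DESeq2 size factors, 67 with a donor block, 67 in thinned libraries, 61 without the 4 libraries and 51 without the low-count filter. Without 1 library, 2049 of 2160 held, 105 were lost and 6 reversed. The cell cycle and immediate early lists in the Th1 and CXCR3 groups reversed without the low-count filter (adjusted p = 0.75 and 0.242). Without the 4 libraries, ribosomal protein (0.000141) and oxidative phosphorylation genes (0.735) in the TSCM pair and monocyte genes in CM against TSCM (0.913) reversed. Without 1 library, the adjusted p in the TSCM pair ranged from 9.55e-09 to 0.926 for ribosomal protein genes, which reversed without TSCM_CCR4 replicate 2 (0.371). It ranged from 1.83e-05 to 0.968 for cytotoxic granule genes, which reversed without TSCM_CCR4 replicate 1 (0.851) and TSCM_CXCR3 replicate 3 (0.968). It ranged from 1.3e-08 to 0.926 for immediate early and from 3.27e-08 to 0.949 for monocyte genes, which reversed without TSCM_CXCR3 replicate 3. For mitochondrially encoded genes in non-naive against naive it ranged from 0.000479 to 0.481, and they reversed without naive replicate 2.

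Without 1 library, the counts ranged from 198 to 469 for non-naive, 166 to 213 for CCR6, 35 to 88 for CM, 155 to 265 for CXCR3_CCR4, 89 to 141 for Th1, 252 to 373 for Th1_17, 225 to 282 for Th17, 177 to 395 for Th2, 2 to 10 for TSCM_CCR4 and 3 to 19 for TSCM_CXCR3 against naive. They ranged from 4 to 19 for CM against TSCM, 0 to 1 for the TSCM pair, 2 to 5 for Th17 against Th1, 0 to 5 for Th1_17 against both, 0 to 2 for CCR6 against CM, 65 to 122, 2 to 6 and 14 to 43 for the groups in the order given, and 0 to 1 for the difference of contrasts. Without 1 library, 208 of 270 counts stayed within 1.5 times, 53 were lower and 9 higher. A library left out leaves fewer samples, and the cause of the other changes was not tested. Depth limits genes near the floor of 0.441 to 1.74 CPM per library.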

Other observations

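The tests of monocyte, B cell, NK cell and platelet genes and of CCR6 were chosen only after the result was seen, and the counts of other splits of the libraries were planned. Where more than 100 splits exist, 100 were used, of which 49 exchanged libraries only within each donor. Only the real grouping reached the real count for the test of all populations (436 genes, 1 of 100 splits, highest other 32) and for non-naive against naive (384, 1 of 100, highest other 257, and 179 within donors). The same held for the CCR6 and Th17 groups (110, 1 of 100, highest other 2) and for the Th2 and CCR4 groups (35, 1 of 100, highest other 1). With a share of splits under 0.05, chance is argued against in each of these, but 100 splits cannot exclude it. Splits also mix libraries of populations that differ, which can raise the spread within groups and lower the counts of the other splits. The share of splits was also under 0.05 for the Th1 and CXCR3 groups (3, 3 of 100, highest other 11, and 3 within donors) and for CM against TSCM (10, 2 of 84, highest other 10, and 2 within donors). In both, another split called as many genes or more, so that chance is made less likely but not excluded. The split with 11 genes in the Th1 and CXCR3 groups may point to a structure of the samples, and which libraries it joined was not examined. Chance cannot be excluded for Th1_17 against Th1 and Th17 (3 genes, 6 of 84 splits, highest other 11). The splits say nothing about chance where the real count was 0, which every split reaches. This holds for CXCR3_CCR4 against Th1 and Th2 (0 genes by edgeR with 809 at an unadjusted p under 0.05 and 0 by DESeq2, 84 of 84, highest other 4) and for the difference between the Th1 and Th2 and the TSCM contrasts (0 genes by edgeR with 960 at an unadjusted p under 0.05 and 17 by DESeq2, 100 of 100). In the last of these a split within donors called 247 genes, which may also point to a structure of the samples and was not examined further.

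Comparisons of 3 libraries with 3 have 10 splits, which are too few for a share under 0.05. Against naive, the real counts and the highest of the other splits were 259 and 0 for CCR6, 89 and 0 for CM, 321 and 0 for CXCR3_CCR4, 165 and 0 for Th1, 430 and 0 for Th1_17, 411 and 0 for Th17, 299 and 0 for Th2, 2 and 4 for TSCM_CCR4, and 22 and 2 for TSCM_CXCR3. They were 0 and 2 for the TSCM pair (with 950 genes at an unadjusted p under 0.05 by edgeR and 13 called by DESeq2), 2 and 8 for Th1 against Th2, 6 and 0 for Th17 against Th1, and 2 and 0 for CCR6 against CM.

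Monocyte transcripts were high in CCR6 replicate 1, TSCM_CXCR3 replicate 3 and Th1_17 replicate 2, with LYZ at 376, 1760 and 796 CPM against a median of 46.7 CPM in 26 other libraries, and S100A9 at 1900, 2730 and 2060 against 133 CPM. LYZ, S100A8 and S100A9 together reached 2763, 5342 and 3149 CPM in these 3, over a limit of 2000 CPM set after seeing them. CM replicate 1, CXCR3_CCR4 replicate 1 and Th1 replicate 3 lay under it with 1605, 1709 and 1734 CPM, and were kept among the other libraries and in the fits without the 4 libraries. Monocytes among the sorted cells are a candidate source, since the 10 other members of the monocyte list were also higher, with a lowest median log2 ratio of 2.83 over the 3 libraries, and CD14 was at 37.2, 147 and 83.5 against 6.57 CPM. RNA of all blood cell types alike is argued against in CCR6 replicate 1. There 13 genes of NK and cytotoxic cells that are on no monocyte or T cell list and usually over the floor of that library had a median log2 ratio of -0.11 (quartiles -0.65 and 0.40), against 2.83 (quartiles 2.51 and 2.94) for 6 such monocyte genes. In Th1_17 replicate 2 it stays open, since the median was 1.78 for 12 such genes and 1.27 for 7 platelet or red cell genes. Against it, PPBP had 0 CPM and the 3 B cell genes over the floor had a median of -1.25 (quartiles -1.99 and -0.59), which are too few to decide, with the other 6 of 9 usually under the floor. It also stays open in TSCM_CXCR3 replicate 3, where the B cell, NK cell and platelet or red cell lists had ratios of 3.14, 3.76 and 2.26. Sorting on T cell markers would remove such cells, and no biological explanation was tested.

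CCR6 itself was near 0 in the population sorted for it, with 7 counts in 17006966 (upper 95% limit 0.848 CPM), against 54 counts in Th17. A wrong label that would place cells low in Th17 genes in these libraries is argued against. The other Th17 genes were higher than in CM in 15 of 15, with a median log2 fold change of 3.10 (p = 2.07e-08 by camera in limma with an estimated correlation, unadjusted for this 1 test). A swap with Th17 or Th1_17 would pass that test as well. CCR4 was at 22.8 ± 5.01 CPM in CCR6 against 331 ± 79.6 in Th17, and CXCR3 at 78.5 ± 43.9 against 316 ± 40.6 in Th1_17 (SD, n = 3). Reads shared with an overlapping gene on the same strand cannot be told apart from low CCR6 transcript levels. In GENCODE release 29, 69.2% of the exonic length of CCR6 is shared in this way, and coding genes with at least 80% shared passed the count filter in 11.8% of 195 against 60.9% of 15544 with none, a ratio of 0.19. CCR6 lies under that limit, among 130 genes with 60 to 80% shared (a range added afterwards), of which 37.7% passed, and the annotation used for counting is not stated.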
